A study of Mus musculus with 6 samples.

How the data were processed

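Mouse nTreg cells (CD4+CD25+CD127lo, spleen, B6.129 strain, 8 to 10 weeks old) from 3 WT and 3 T cell Srsf1-knockout mice were stimulated for 72 h with anti-CD3 (2 µg/ml), anti-CD28 (2 µg/ml) and recombinant interleukin-2 (10 ng/ml), per the labels' protocols. Groups and replicate numbers were taken from the sample titles. The labels' source field names effector CD4 T cells, while the titles, the sorting protocol and the design text name nTreg cells, and the latter were followed. Stranded mRNA libraries were read as 75-bp single ends and processed with the VIPER pipeline, per the series' design text. The genome build was mm9, per the submitters' processing notes, and reads were aligned with STAR 2.4.2a, per the file headers. The counting tool, its strand setting and the annotation are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart.

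The authors deposited whole-number counts per gene symbol for 24982 symbols, not normalized, 1 column per library. A second table deposited by the authors holds FPKM values for 24917 of these symbols, which are normalized for length and depth. The alignment report deposited by the authors gives read totals and percent values per library: uniquely mapped reads were 77.45% to 81.33% of input, and the mismatch rate was 0.52% in KO replicate 1 against 0.32% to 0.43% in the others. The count table uses capital letters, and 24827 symbols were matched to reference mouse symbols for display. In 26 entries a date stands in place of a symbol, which hold 0.271% of all counts and were kept in the library sizes but not named. Coordinates are not given, since the annotation at hand is of another build; it was used only for symbols and for the GC content and length of transcripts.

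Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM normalization, filterByExpr defaults with a minimum count of 10, quasi-likelihood F test, Benjamini-Hochberg adjustment, threshold 0.05), which left 11772 genes. CPM are TMM-normalized. Standard errors of log2 fold changes were taken from the F statistic. All adjusted p of genes in the text come from this test unless DESeq2 1.42.0 or limma 3.58.1 is named. Gene lists were tested with camera in limma on voom values, with a preset correlation of 0.01, for the 30 of 35 lists with at least 5 tested members, adjusted over the lists. Of 15 lists called, 11 higher and 4 lower in KO, 0 were called with the correlation estimated from the data, a test that also has only 4 degrees of freedom. With each list's estimate as a fixed value, an alternative added later, 6 were called. The fry test called 2 lists by direction, Treg identity (adjusted p = 0.0237) and macrophage markers (0.0324), both higher in KO. In either direction it called 6 lists. The design, the lists, the rule for named genes and the first set of alternatives were fixed before the data were examined.

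The rule named Srsf1, Foxp3, Il2ra, Ctla4, Il10, Ifng, Il4, Il17a and Rps6kb1, the 12 higher and 12 lower genes with the largest changes among those past the threshold with at least 2 CPM and no overlap between groups (or, if none passed in a direction, the 6 with the smallest p, as values only), leaving out predicted genes, pseudogenes and receptor segments, and up to 4 members of each list with the smallest p. Gzmb, Serpinb6b and Il24 were named after their values were seen. Some genes that the rule or the lists include are not reported here. The alternatives fixed beforehand were DESeq2 size factors, upper quartile or library size scaling, no filter, a minimum of 1 CPM in 3 libraries, the DESeq2 Wald test, voom, the replicate number as a block, each library left out in turn, and limma on log2(FPKM + 1) or log2(FPKM + 0.1), with and without a filter of 1 FPKM in 3 libraries. Alternatives added after the data were seen were a correction for GC content and length, sex as a covariate, both together, voom with quality weights, 2 against 2 libraries (without KO replicate 1 and the library labelled WT replicate 3), thinning to equal depth, and leaving out the ribosomal RNA gene Rn45s.

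Total counts ran from 10183626 to 27562046 per library, so that 3 counts correspond to 0.109 to 0.295 CPM before normalization. No pair of libraries agreed within sampling noise, with chi-square per degree of freedom of 22.0 to 375. The libraries are taken to come from separate animals, so these values do not measure library quality. The pipeline was tested on simulated data made from these libraries' means and spread: for 11640 genes edgeR made 2 false calls and DESeq2 31, with 70.7% and 87.9% of 4-fold changes recovered. Of 200 simulated lists without a change, 6 had a camera p under 0.05. Genes in these lists were drawn independently, so the check does not cover lists whose members vary together. Estimated correlations of the tested lists reached 0.708, for replication-dependent histones.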

Results

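RNA was sequenced from natural regulatory T cells (nTreg cells), the CD4+CD25+CD127lo T cells that restrain other immune cells, sorted by flow cytometry from mouse spleen. The cells came from wild-type (WT) mice and from mice lacking the splicing factor Srsf1 in T cells (KO). All were stimulated for 72 h with antibodies to CD3 and CD28 and with interleukin-2. Each group had 3 libraries. The series' design text gives 3 mice per genotype, so the replicates are taken to be separate animals. Total gene counts were 23263741, 25908166 and 27562046 for WT replicates 1, 2 and 3, and 20373649, 13241964 and 10183626 for KO replicates 1, 2 and 3. Each KO library was thus shallower than each WT library. KO replicate 1 stood apart: its log2 CPM correlated across genes with the other libraries at r = 0.900 to 0.927, against 0.945 to 0.989 among the other 5.

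The comparison asked how loss of Srsf1 changes gene expression in stimulated nTreg cells. Srsf1, the targeted gene, was measured at 1214, 1230 and 755 CPM (normalised counts scaled to a common library size) in the libraries labelled WT replicates 1, 2 and 3, and at 438, 812 and 787 CPM in KO replicates 1, 2 and 3. The library labelled WT replicate 3 therefore lay below KO replicates 2 and 3. The log2 fold change in KO against WT was -0.65 (SE 0.32), with an adjusted p of 0.682 in edgeR's quasi-likelihood test. An exact two-sided permutation test gave p = 0.3, where 3 against 3 libraries allow no p below 0.1. Counts over the whole gene include exons outside any deleted part, so these values neither assign nor exclude a genotype. Directions below follow the labels, including that of the library labelled WT replicate 3.

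The clearest differences were lower values of Cd8b1 and Dapl1 in the KO libraries. Whether they reflect a change within the cells or a different share of CD8 T cells between the groups was not tested for these genes. Cd8b1, which encodes the beta chain of the CD8 coreceptor, fell from 85.3 ± 9.16 CPM in WT to 13.3 ± 0.907 CPM in KO (mean ± SD, n = 3 each; log2 fold change -2.68, SE 0.23, edgeR adjusted p = 0.0166). Dapl1, a gene of resting T cells, fell from 34.7 ± 9.14 to 3.56 ± 0.441 CPM (log2 fold change -3.29, SE 0.33, edgeR adjusted p = 0.0295). Foxp3, the transcription factor that defines Treg cells, was at 160, 121 and 104 CPM in WT and 464, 357 and 413 CPM in KO. Its log2 fold change of +1.68 (SE 0.25) did not pass the threshold (edgeR adjusted p = 0.197).

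**Figure D1:**
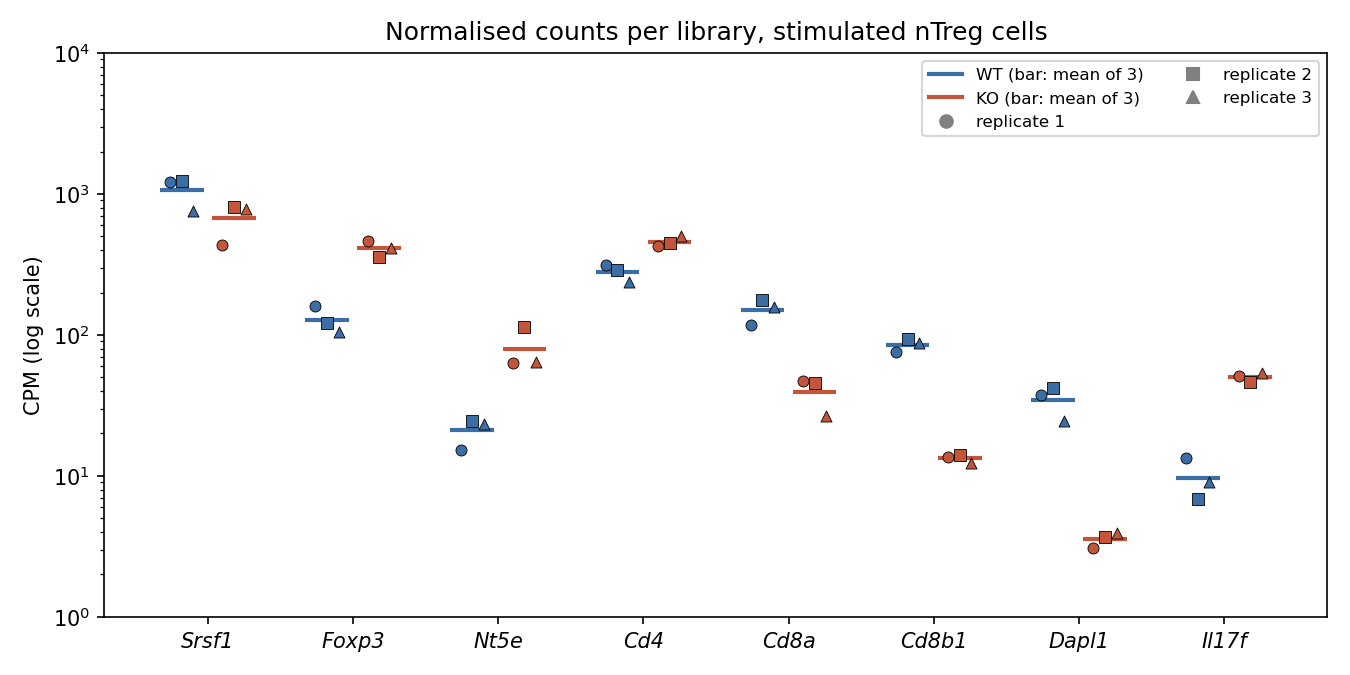
Normalised counts (CPM, log axis) of 8 genes in the 6 libraries. Points are libraries, with a marker shape per replicate number, and bars are the means of 3. For Cd8b1 and Dapl1 the 3 KO points lie below the 3 WT points, for Foxp3 they lie above (357 CPM or more against 160 CPM or less), and for Srsf1 the groups overlap.

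Of 11772 genes tested, edgeR called these 2, both lower in KO and both changed by more than 2-fold, and 884 genes had an unadjusted p under 0.05 (559 higher, 325 lower). DESeq2 called 129 genes (94 higher, 35 lower), both of these among them. The groups did not overlap for 1843 genes, 15.7% of those tested, where chance gives 10%. No gene passed in the upward direction, so the 6 with the smallest p are given as values only. Besides Foxp3, these were Myo1e (log2 fold change +1.91, SE 0.24), a motor protein, Il17f (+2.37, SE 0.31), a cytokine of the T helper 17 type, Igfbp7 (+2.21, SE 0.31), Nav2 (+2.85, SE 0.42) and Fam167a (+4.25, SE 0.67, from 0.0964 to 1.87 CPM). Their edgeR adjusted p ranged from 0.109 for Myo1e to 0.212 for Fam167a. Among the other genes fixed in advance, Il2ra stood at -0.09, Ctla4 at -0.79, Il10 at +0.16, Ifng at +0.30, Il4 at +0.74, Il17a at +2.21 and Rps6kb1 at -0.26 on the log2 scale, none past the threshold, and Ctla4 stood at -0.20 without the library labelled WT replicate 3.

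These calls had little margin. Without WT replicate 1 or 2, the library labelled WT replicate 3, KO replicate 2 or KO replicate 3, edgeR called 0 genes (509 to 1272 at an unadjusted p under 0.05). With sex of the animal as a covariate it also called 0 (695 at an unadjusted p under 0.05), but with the GC and length correction added to sex both genes passed (edgeR adjusted p = 0.00244 for Cd8b1 and 0.0111 for Dapl1), while without KO replicate 1 it called 3, with Myo1e as the added gene. For Cd8b1 the edgeR adjusted p without 1 library ranged from 0.00808 (KO replicate 1 left out) to 0.220 (WT replicate 2 left out), and for Dapl1 from 0.0335 (KO replicate 1 left out) to 0.268 (KO replicate 2 left out). The log2 fold changes moved little, from -2.77 to -2.61 for Cd8b1 and from -3.50 to -3.13 for Dapl1 with 1 library left out, and to -2.67 and -3.28 with the sex covariate. On counts simulated at the spread of these libraries, for 11640 genes, the test recovered 6.12% of 2-fold and 70.7% of 4-fold changes.

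The list of Treg identity and suppression genes was called higher in KO by camera, though not with an estimated correlation. Of 43 tested members of this list, 35 had a fold change above 0, with a median log2 fold change of +0.54. Beyond Foxp3, the leading members were Nt5e (+1.93, SE 0.33), whose product CD73 makes adenosine, Il1rl1 (+1.58, SE 0.29), the interleukin-33 receptor, and the decoy receptor Il1r2 (+1.27, SE 0.31). The list also holds Il2ra (-0.09) and Ctla4 (-0.79), both below 0, and Il10 (+0.16). Over all genes tested 0 members passed, and adjusted over the list alone 12 were higher and 1, the granule protease Gzmb (-1.20, SE 0.34), was lower. The camera adjusted p was 1.01e-08, and the adjusted p = 0.0654 with an estimated correlation, while the fry adjusted p by direction was 0.0237. In the same libraries Cd8b1 fell, Cd8a stood at -1.92 (SE 0.29) and Cd4 at +0.70 (SE 0.23), the last 2 not past the threshold.

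**Figure D2:**
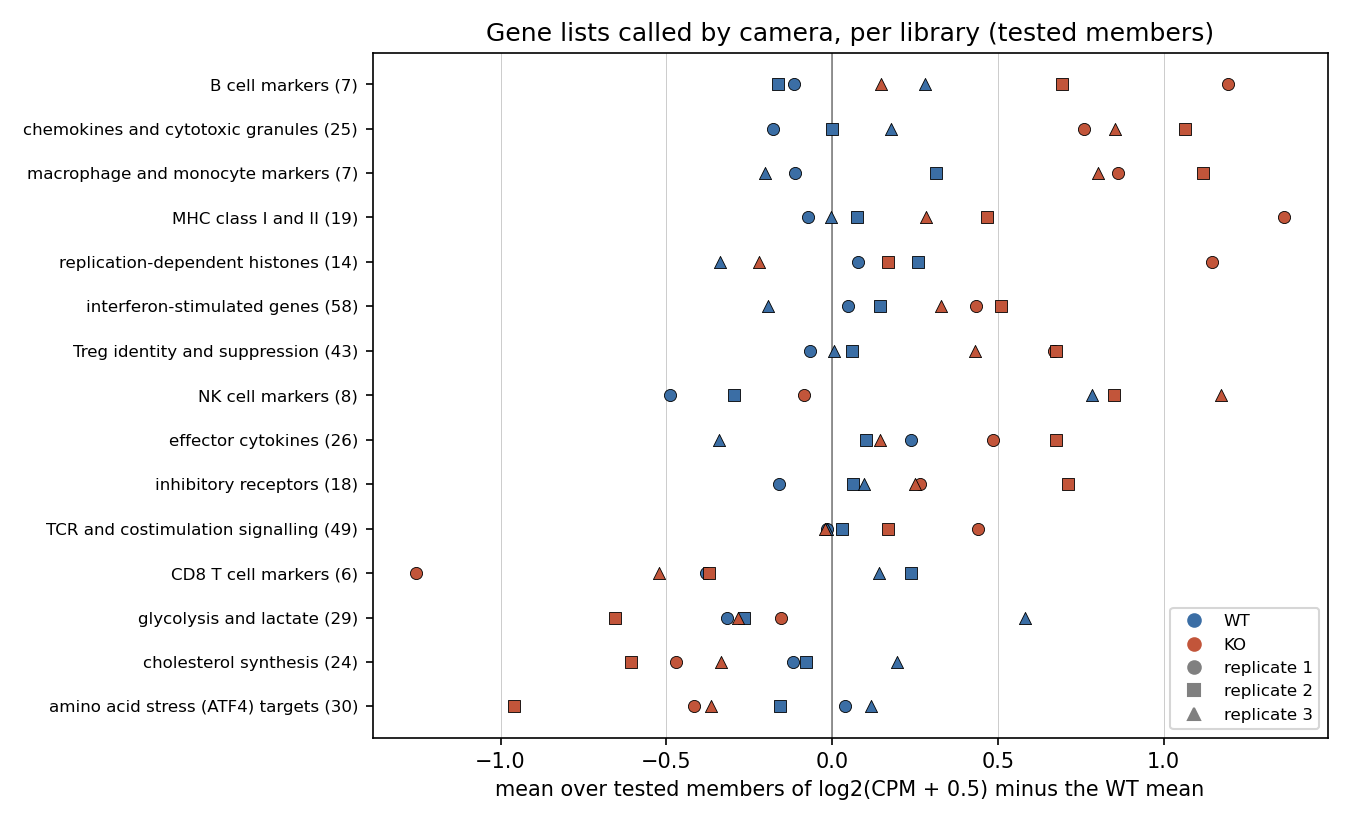
The 15 gene lists called by camera, with the number of tested members in brackets. Each point is 1 library: the mean over members of log2(CPM + 0.5) minus the mean of the WT libraries. For Treg identity and for the ATF4 targets the 3 KO libraries lie on 1 side of the 3 WT libraries, while for the histones KO replicate 1 alone lies far from the rest.

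Both lists of secreted effector molecules were called higher by camera, with members on either side of 0. In the list of chemokines and cytotoxic granules, 19 of 25 tested members were above 0 (median +1.02), led by the granzyme Gzmc (+2.02, SE 0.41) and the chemokines Ccl22 (+3.09, SE 0.75), Ccl1 (+5.41, SE 1.32) and Ccl3 (+1.86, SE 0.47). Adjusted over the list alone, 9 members were higher and 2, Gzmb and Serpinb6b, lower, against 0 over all genes (camera adjusted p = 0.000849, and adjusted p = 0.208 with an estimated correlation). Gzmb, more abundant than Gzmc, was at 5699.7 CPM in WT and 2484 CPM in KO, against 53.8 and 218 CPM for Gzmc. Single libraries set the size of 2 chemokine values: Ccl22 stood at +1.82 without KO replicate 2, and Ccl1 at +4.56 without KO replicate 2 and +7.10 without WT replicate 2. Effector cytokines had 17 of 26 members above 0, with Il17f, Il17a, the lymphotoxin gene Lta (+0.999, SE 0.25) and Csf1 (+1.88, SE 0.48) leading. Adjusted over the list alone 4 were higher and 1, Il24 (-1.49), was lower, against 0 over all genes. That list's camera adjusted p of 0.00481 became 0.305 as adjusted p with an estimated correlation, 0.0697 without the library labelled WT replicate 3 and 0.102 without KO replicate 2. Library means of the effector cytokines overlapped: relative to the WT mean on the log2 scale, KO replicate 3 stood at 0.14 and WT replicate 1 at 0.24.

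Inhibitory receptors rose as a list, with 13 of 18 tested members above 0, led by Havcr2 (+1.39, SE 0.30), which encodes TIM-3, Klrg1 (+2.44, SE 0.68), the T cell surface protein Cd5 (+1.07, SE 0.31) and Cd200r1 (+1.19, SE 0.40). Adjusted over the list alone 3 were higher, against 0 over all genes (camera adjusted p = 0.00800, adjusted p = 0.361 with an estimated correlation, and 0.279 without KO replicate 2). Klrg1 stood at +1.75 without KO replicate 2 and +3.18 without WT replicate 2. Genes of T cell receptor and costimulation signalling rose as a list too, with 35 of 49 above 0 (median +0.32), and with the ubiquitin ligase Cblb (-0.81, SE 0.23), Cd3e (+0.68, SE 0.22), Cd4 and Nfatc1 (+0.90, SE 0.29) at its head. No member passed over all genes or adjusted over the list alone (camera adjusted p = 0.0135, adjusted p = 0.449 with an estimated correlation). Library means of the signalling list overlapped, with KO replicate 3 at -0.02 and WT replicate 2 at 0.03 relative to the WT mean on the log2 scale. That call ended without KO replicate 1 (adjusted p = 0.258), KO replicate 2 (0.0739) or the library labelled WT replicate 3 (0.0543), and after correction for GC content and length (0.1005).

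The lists of interferon-stimulated genes and of antigen presentation genes were called higher in KO by camera. Of 58 interferon-stimulated genes tested, 46 were above 0 (median +0.54). They included the antiviral genes Oasl2 (+2.60, SE 0.55, 0.312 to 1.89 CPM) and Zbp1 (+1.13, SE 0.26) and the GTPase Gbp3 (+1.16, SE 0.28). In contrast, Ifit1 stood at -1.76 (SE 0.43). Adjusted over the list alone 6 were higher and 1 lower, against 0 over all genes (camera adjusted p = 2.25e-06, adjusted p = 0.289 with an estimated correlation). Among 19 tested genes of MHC class I and II, 18 were above 0 (median +0.66), led by H2-Aa (+2.76, SE 0.60, 0.657 to 4.43 CPM), H2-Q4 (+1.04, SE 0.26), H2-Eb1 (+1.70, SE 0.43) and the invariant chain Cd74 (+1.72, SE 0.54). Adjusted over the list alone 3 were higher, against 0 over all genes (camera adjusted p = 3.51e-07, adjusted p = 0.361 with an estimated correlation). The MHC shift was largest in KO replicate 1, the library that stood apart, with a list mean of 1.36 on the log2 scale relative to the WT mean, against 0.47 and 0.28 in KO replicates 2 and 3. Without KO replicate 1 the camera adjusted p was 0.000552, and Cd74 stood at +1.09. H2-Q4 has near-identical relatives, and H2-Q6 and H2-Q7 were at 0 in all libraries, so its value is uncertain.

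The lists of ATF4 targets, cholesterol synthesis and glycolysis were called lower in KO by camera, while oxidative phosphorylation was not called (29 of 59 members above 0, camera adjusted p = 0.520) unless KO replicate 1 was left out, when it passed as lower (adjusted p = 1.72e-07). Targets of ATF4, the transcription factor of the amino acid stress response, had 5 of 30 members above 0 and a median of -0.56. The leading members were the asparagine synthetase Asns (-1.45, SE 0.37), Trib3 (-1.48, SE 0.41), and the serine synthesis genes Psph (-0.91, SE 0.26) and Psat1 (-0.68, SE 0.21). Cholesterol synthesis had 4 of 24 members above 0 (median -0.49), led by Fdps (-0.99, SE 0.31), Acat2 (-0.82, SE 0.26) and Stard4 (-0.85, SE 0.28). Glycolysis and lactate had 5 of 29 above 0 (median -0.39), led by Pdk1 (-1.03, SE 0.36), Vegfa (-1.39, SE 0.50) and Ero1l (-1.70, SE 0.62). The list also holds genes that do not encode enzymes of glycolysis itself, and these 3 are among them. The lactate dehydrogenase gene Ldhb stood at +0.75 (SE 0.29). Ero1l stood at -0.58 without the library labelled WT replicate 3, and Vegfa at -2.09 without KO replicate 3. In none of the 3 lists did a member pass over all genes or adjusted over the list alone. The camera adjusted p was 1.13e-07 for ATF4 targets, 2.36e-06 for cholesterol synthesis and 0.00315 for glycolysis, against adjusted p = 0.332, 0.289 and 0.665 with an estimated correlation. Library means overlapped for glycolysis: relative to the WT mean, KO replicate 1 stood at -0.15 on the log2 scale, against -0.32 and -0.27 for WT replicates 1 and 2. The glycolysis call ended without the library labelled WT replicate 3 (adjusted p = 0.264) or KO replicate 2 (0.180).

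Lists of other cell types' markers were called in both directions, and library means overlapped between the groups in 3 of them, given here relative to the WT mean on the log2 scale. For CD8 T cell markers KO replicate 2 stood at -0.37 and WT replicate 1 at -0.38, and for B cell markers KO replicate 3 at 0.15 and the library labelled WT replicate 3 at 0.28. For NK cell markers KO replicate 1 stood at -0.08 and the library labelled WT replicate 3 at 0.79, near KO replicate 2 at 0.85. CD8 T cell markers fell as a list of 6 tested genes, 1 of them above 0, of which Cd8a and Cd8b1 were lower adjusted over the list alone and Cd8b1 over all genes, while Eomes (+0.85, SE 0.34) and Klrk1 (-0.12, SE 0.38) did not follow (camera adjusted p = 0.0119, adjusted p = 0.420 with an estimated correlation). Its call ended without KO replicate 1 (adjusted p = 0.588) or WT replicate 2 (0.0959), and after correction for GC content and length (0.1005). B cell markers rose as a list of 7 tested genes, 4 of them above 0 (camera adjusted p = 0.0119, adjusted p = 0.361 with an estimated correlation, and 0.0670 without KO replicate 1). That call also ended with a minimum of 1 CPM in 3 libraries (adjusted p = 0.0545) and at equal depth (0.0583). The 4 genes higher adjusted over the list alone, against 0 over all genes, were H2-Aa, H2-Eb1, Cd74 and the kinase Blk (+2.53, SE 0.74), and the first 3 of them are also in the MHC list. Blk was at 0.173 CPM in WT and 0.983 CPM in KO. Without KO replicate 1, Blk stood at +1.54 and Cd74 at +1.09. The B cell genes Ms4a1 and Cd79a had at most 4 counts in any library. Macrophage and monocyte markers rose as a list of 7 tested genes, 6 of them above 0, led by Fcer1g (+2.59, SE 0.50, 1.03 to 6.27 CPM), Cd68 (+1.15, SE 0.46), Vcam1 (+1.39, SE 0.83) and Ccr2 (+0.78, SE 0.49), with only Fcer1g higher adjusted over the list alone and 0 over all genes (camera adjusted p = 0.00190, adjusted p = 0.224 with an estimated correlation). Vcam1 stood at +2.58 without WT replicate 2 and Ccr2 at +0.05 without KO replicate 2. Csf1r, C1qa and Lyz2 were listed at 0 in all libraries, but so was Rpl26, a ribosomal protein gene used by every cell, so these zeros may be missing values and say nothing of macrophage content. Among listed markers that did have counts, Adgre1, Cd14, Itgam and Spi1 had at most 4 in any library, Tyrobp 10 and Fcgr3 12. These low counts argue against a large share of macrophages in any library, while Fcer1g and Cd68 stood higher in KO without passing over all genes.

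NK cell markers rose as a list of 8 tested genes, 6 of them above 0, led by Klrb1b (+2.32, SE 0.65), Klrb1c (+1.94, SE 0.70), Eomes and Klra7 (+1.11, SE 0.71), with 0 genes passing over all genes or adjusted over the list alone (camera adjusted p = 0.0232, adjusted p = 0.590 with an estimated correlation). Levels were low, with Klrb1b at 0.481 CPM in WT and 2.45 CPM in KO, and Klrb1c at 0.389 and 1.55 CPM. Klrb1b stood at +1.53 without KO replicate 2, and Klrb1c at +2.97 and Klra7 at +2.001 without the library labelled WT replicate 3. That call ended without WT replicate 1 (adjusted p = 0.0565), KO replicate 2 (0.176) or KO replicate 3 (0.277), and with a minimum of 1 CPM in 3 libraries (0.0734). Replication-dependent histones, whose mRNAs mostly lack a poly(A) tail, rose as a list of 14 tested genes, 13 of them above 0, led by Hist1h1c (+1.44, SE 0.54), Hist1h3c (+2.45, SE 1.05), Hist1h4b (+1.35, SE 0.71) and Hist1h2bj (+1.37, SE 0.73), with 0 genes passing over all genes or adjusted over the list alone (camera adjusted p = 0.0219, adjusted p = 0.696 with an estimated correlation). Library means of the histones overlapped, with KO replicate 3 at -0.22 and WT replicate 2 at 0.26 relative to the WT mean. Hist1h3c was at 0.415 CPM in WT and 2.21 CPM in KO, and Hist1h4b at 0.473 and 1.16 CPM. Without KO replicate 1, Hist1h3c stood at -0.05, Hist1h4b at +0.35 and Hist1h2bj at +0.15. The histone call ended without KO replicate 1 (adjusted p = 0.901) or the library labelled WT replicate 3 (0.303), and with a minimum of 1 CPM in 3 libraries (0.0639).

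The other 15 tested lists did not pass in camera. Helper lineage transcription factors came closest (21 of 32 above 0, camera adjusted p = 0.0729), with Runx1 (+0.77, SE 0.22), Tox (+1.21, SE 0.34) and Bhlhe40 (-0.55, SE 0.25) as examples. Next was the SR protein list (5 of 22 above 0, camera adjusted p = 0.0824), with Srsf12 at -1.66 (SE 0.52) and Srrm2 at +0.44 (SE 0.22). It holds the splicing factor family of Srsf1, without Srsf1 itself, and also related proteins and kinases. The camera adjusted p was 0.107 for p53 targets, 0.199 for ribosomal proteins, 0.349 for the unfolded protein response, 0.423 for immediate early and heat shock genes, 0.520 for each of oxidative phosphorylation, S phase and dendritic cell markers, 0.682 for hnRNPs and core spliceosome and for PI3K-AKT-mTOR regulators, 0.835 for nonsense-mediated decay, 0.908 for apoptosis regulators and for G2 and M phase, and 0.983 for the naive and homing program. Members above 0 were 21 of 33 for p53 targets, 38 of 76 for ribosomal proteins, 10 of 24 for the unfolded protein response, 13 of 21 for immediate early and heat shock genes, 29 of 59 for oxidative phosphorylation, 26 of 40 for S phase, 4 of 5 for dendritic cell markers, 23 of 48 for hnRNPs, 24 of 42 for PI3K-AKT-mTOR regulators, 13 of 23 for nonsense-mediated decay, 16 of 31 for apoptosis regulators, 23 of 40 for G2 and M phase and 14 of 25 for the naive and homing program. Among these 15 lists only the naive and homing program had a member that passed, over all genes or adjusted over the list alone. In it, adjusted over the list alone, Dapl1 and the chromatin organiser Satb1 (-1.02, SE 0.25) were lower and the transcription factor Klf2 (+2.62, SE 0.67) was higher, against Dapl1 alone over all genes. Klf2 stood at +1.58 without KO replicate 1. For ribosomal proteins, oxidative phosphorylation and the hnRNP list the test and the median pointed down while the mean lay above 0. Fry gave the naive and homing list a direction opposite to that of camera, down against up (median +0.14). Its fry adjusted p was 0.793 by direction, but 0.0199 for changes in either direction, which passed. Without KO replicate 1, ribosomal proteins (adjusted p = 8.48e-10) and oxidative phosphorylation (1.72e-07) passed as lower and G2 and M phase (0.0129) as higher. Without the library labelled WT replicate 3, SR proteins and the hnRNP list passed as lower (0.0385 each), SR proteins also did so without KO replicate 3 (0.0165), and p53 targets passed as higher without WT replicate 2 (0.0177) or KO replicate 3 (0.0401). After the correction for GC content and length, p53 targets passed as higher (0.00395, and 0.00328 with sex) and ribosomal proteins as lower (0.0277, and 0.0364 with sex). Lists of plasma cell, gamma-delta T cell, granulocyte, erythroid and platelet, and stromal and endothelial markers had 1, 4, 2, 1 and 3 tested genes and were not tested as lists. Adjusted over the list alone, Blk was higher among the gamma-delta markers, which it shares with the B cell list, and 0 genes passed in the other 4.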

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

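The GC and length correction, the sex covariate, both together, voom with quality weights, the 2 against 2 comparison, thinning to equal depth, leaving out Rn45s and using each list's estimated correlation as a fixed value were chosen after the results were seen, the 2 against 2 comparison because its left-out libraries, KO replicate 1 and the library labelled WT replicate 3, stood apart. The count of 2 genes called was the same with DESeq2 size factors, upper quartile scaling, library size only, 1 CPM in 3 libraries, FPKM with either pseudocount and a filter, thinning and leaving out Rn45s. It became 129 with DESeq2 (124 of them 2-fold), 6 without a filter, 1 with voom, 0 with unfiltered FPKM, 11 after the GC and length correction, 0 with the sex covariate, 10 with both, 229 with quality weights (172 of them 2-fold) and 80 in the 2 against 2 comparison (64 of them 2-fold). Leaving out 1 library gave 0 to 3 genes. The 2 genes were both among the calls in each setting with 2 or more. Same-numbered libraries deviated from their group means with r = -0.36, 0.15 and 0.14, which does not settle whether the numbers pair the samples. Sex did match by number, with replicate 2 male and replicates 1 and 3 female in both groups. The fit with the replicate number as a block called 1 gene, Ccl1, and 15 lists. The Srsf1 log2 fold change stayed below 0 in all settings, from -0.85 without the library labelled WT replicate 3 to -0.37 with GC correction and sex, and passed in none. The count of 15 lists became 0 with an estimated correlation, 6 with each list's estimate as a fixed value (Treg identity, chemokines, macrophage markers, interferon-stimulated genes, cholesterol synthesis and effector cytokines) and 10 to 16 with 1 library left out. For changes of direction the cause was not tested, except that removing libraries leaves fewer samples. Low depth limits genes of few counts, and the 3 shallowest libraries are the KO libraries.

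All direction changes among named genes concerned values that did not pass the edgeR test in the first place. After the GC and length correction, alone and with sex, Il2ra stood at 0.12 and 0.13, Klrk1 at 0.10 and 0.12, Pold1 at -0.044 and -0.039, Rps6kb1 at 0.025 and 0.022, and Il23r at 0.21 and 0.43, while Car2 with both stood at 0.20. With the sex covariate alone, Car2 stood at 0.42 and Il23r at 0.063. With quality weights, Bst2 stood at -0.30, Cd163l1 at -0.52, Cox8a at -0.16, Hist1h3c at -0.13, Il23r at 1.30, Il2ra at 0.19, Klrk1 at 0.27, Pold1 at -0.17 and Rpl13 at -0.021. In the 2 against 2 comparison, Bst2 stood at -0.46, Cox8a at -0.21, Ctla4 at 0.094, Hist1h3c at -0.32, Il23r at 1.65, Il2ra at 0.33, Klrk1 at 0.26, Pold1 at -0.25, Rpl13 at -0.037, Rps6kb1 at 0.00089 and Syvn1 at -0.059. Car2 stood at 0.023 with upper quartile scaling, 0.032 with library size only, 0.58 with voom, 0.49 with the replicate block, 0.36 in FPKM with pseudocount 1 with or without a filter, and 0.51 with pseudocount 0.1. Il23r stood at 0.34 with voom, 0.40 with the replicate block and 0.026 with unfiltered FPKM. With 1 library left out, the ranges were -0.38 to 0.90 for Bst2, -0.56 to 1.23 for Car2, -0.9996 to 0.79 for Col1a1, -0.25 to 1.02 for Cox8a, -0.049 to 2.97 for Hist1h3c, -0.13 to 0.57 for Ifng, -0.52 to 1.35 for Il23r, -0.39 to 0.14 for Il2ra, -0.33 to 0.20 for Klrk1, -0.14 to 0.80 for Pecam1, -0.35 to 1.04 for Pold1, -0.086 to 1.24 for Rpl13, -0.56 to 0.067 for Rps6kb1 and -0.10 to 1.09 for Syvn1.

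Among lists, the histones pointed down in the 2 against 2 comparison (adjusted p = 0.3601), as did S phase (0.138), dendritic cell markers (0.794) and immediate early genes (0.255), and the hnRNP list pointed up after the GC and length correction, alone (0.393) and with sex (0.408). G2 and M phase pointed down with the replicate block (0.934), and the naive and homing program with library size only (0.956). With 1 library left out, the adjusted p of lists that pointed both ways ranged from 0.0129 to 0.867 for G2 and M phase, 0.0966 to 0.809 for S phase, 0.0165 to 0.987 for SR proteins, 0.572 to 0.978 for apoptosis regulators, 0.202 to 0.698 for dendritic cell markers, 0.0385 to 0.965 for the hnRNP list, 0.170 to 0.704 for immediate early genes, 0.617 to 0.980 for the naive and homing program, 0.517 to 0.853 for nonsense-mediated decay, 1.72e-07 to 0.980 for oxidative phosphorylation and 8.48e-10 to 0.813 for ribosomal proteins. Apart from left-out libraries and estimated correlations, list calls also ended for TCR and costimulation signalling with both corrections (0.0824) and in the 2 against 2 comparison (0.154), for CD8 T cell markers likewise (0.126 and 0.634), and for the histones at equal depth (0.0500053). In the 2 against 2 comparison, ribosomal proteins (4.83e-08) and oxidative phosphorylation (4.64e-09) passed as lower. Over 30 lists, 51 of 540 values lost a call with the same direction and 14 gained one, and over the named genes apart from Srsf1, 17 of 3168 values lost a call, all of Cd8b1 or Dapl1, and 99 gained one.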

Other observations

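The genes of the first 2 paragraphs, the splits of the samples and the tests of the 3 patterns after them were chosen after their results were seen. The cytochrome P450 gene Cyp1a1 was at 0.628 ± 0.497 CPM in WT and 8.44 ± 5.94 CPM in KO (mean ± SD, n = 3 each), a log2 fold change of +3.76 (SE 0.86), and Cyp1b1 was at 0.0844 ± 0.0736 and 1.94 ± 1.10 CPM (+4.47, SE 0.87). Zbtb16, which encodes the innate-like T cell factor PLZF, was at 6.31 and 23.05 CPM (+1.87, SE 0.38), and the ion channel genes Tmem176a and Tmem176b stood at +2.13 (SE 0.45) and +2.12 (SE 0.37). With 1 library left out, Cyp1a1 stood at +3.16 (KO replicate 1) or +4.45 (WT replicate 2) and Cyp1b1 at +3.86 (the library labelled WT replicate 3). None of these passed edgeR's test, with adjusted p from 0.235 to 0.350, while DESeq2 called all 5. In WT, Cyp1b1 lay near the level of 3 counts or below. Ahrr (+0.95), Tiparp (-0.69), Nqo1 (+0.46) and Ahr (-0.36), looked up beside Cyp1a1 and Cyp1b1, were called by neither test.

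After the correction for GC content and length, edgeR called 11 genes, 7 higher and 4 lower. Beside Cd8b1 and Dapl1 these were Myo1e (+1.82, adjusted p = 0.0124), Il17f (+2.52, 0.0168), Havcr2 (+1.56, 0.0353), the membrane protein Ldlrad4 (+1.62, 0.0441), Nt5e (+1.96, 0.0441), Nav2 (+2.401, 0.0441) and the interferon-induced GTPase Gbp7 (+1.34, 0.0441), and, lower, Arhgdig (-2.13, 0.0353) and the fucosyltransferase Fut4 (-1.64, 0.0441). Y-linked genes were present in WT replicate 2 and KO replicate 2 and Xist in the other 4 libraries (Ddx3y counts 2692 and 1690, at most 1 elsewhere), so each group held 1 male and 2 female samples. The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split alone (1 of 10) gave as many genes as 2 with edgeR (highest other 0, likewise for 2-fold genes), 129 with DESeq2 (highest other 12), 11 after the GC correction (highest other 0) and 15 lists, where the highest other gave 14.

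KO replicate 1 stood apart from the other 5 libraries, with 2099 genes at least 2-fold above their mean and 1803 below. Low depth of that library is argued against, since its 20373649 counts exceeded those of KO replicates 2 and 3 (13241964 and 10183626). With all libraries thinned to equal depth its root mean square log2 deviation was still 0.982, against at most 0.605 in the others. B cells are argued against too, since 4 of their abundant transcripts summed to 4.75 CPM there, against 0.702 to 4.23 in the others, while other cell types were not tested and Cd74 stood at 140.3 CPM there, against at most 71.2 CPM elsewhere. A GC bias of that library may account for the pattern: across genes its deviation correlated with GC content at a Spearman rho of 0.829, against -0.593 to -0.133 in the others. The others were each compared with a mean that held KO replicate 1, so their values are no independent baseline. Correction lowered the deviation of KO replicate 1 to 0.579, against 0.654 in the library labelled WT replicate 3. The correction removes each library's own trend with GC content and length, so some decrease was built in. No biological explanation was tested, as the labels give none for a single replicate.

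Foxp3 and the Treg list were higher in KO while Cd8a and Cd8b1 were lower, in cells sorted as CD4+CD25+CD127lo, a gate that should remove CD8 T cells. More CD8 T cells in the WT libraries as the whole cause of the Foxp3 difference is argued against, since Foxp3 exceeded Cd4 by 0.99 on the log2 scale (SE 0.17, exact two-sided permutation p = 0.1, the smallest possible), but for the list this stays open, as its median lay -0.16 from the log2 fold change of Cd4. GC bias of KO replicate 1 is argued against for the list, with adjusted p = 2.37e-11 after correction (2.77e-13 to 5.30e-06 over the settings with a preset correlation), and Foxp3 stood at +1.48 (edgeR adjusted p = 0.0666, against 1.59e-06 with DESeq2 to 0.793 without the library labelled WT replicate 3). A larger share of conventional CD4 T cells in WT cannot be told apart from a change within Treg cells, as the naive and homing list had a median of 0.14 (SE 0.25) with members moving both ways. Loss of Srsf1 stays open as well, and the estimated correlation of the list's members, 0.00336, lay below the preset 0.01, so the adjusted p = 0.0654 with an estimated correlation came with the 4 degrees of freedom of that test, against 7.54e-11 with the same estimate as a fixed value.

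The lists of ATF4 targets and cholesterol synthesis were called lower in KO by camera with the preset correlation, but not with an estimated one. Lower depth of the KO libraries is argued against, since after thinning to equal depth the larger adjusted p of both lists was 2.53e-06. GC bias of KO replicate 1 is argued against as well, with 2.62e-09 as the larger adjusted p after correction. Over all settings with a preset correlation the largest adjusted p was 0.00180, for ATF4 targets without KO replicate 2. Other splits of the libraries also gave small unadjusted camera p. For ATF4 targets it fell to 5.28e-07, with WT replicate 1, the library labelled WT replicate 3 and KO replicate 1 on 1 side. For cholesterol synthesis it fell to 5.74e-06, with WT replicate 1 and KO replicates 1 and 2 on 1 side. The real split gave 7.56e-09 and 3.93e-07, the smallest of the 10. Members varying together between libraries cannot be told apart from a group difference, as the estimated correlations were 0.262 for ATF4 targets and 0.131 for cholesterol synthesis, and as fixed values they gave an adjusted p of 0.0937 and 0.0296, against 0.332 and 0.289 where the correlation is estimated within the test. Loss of Srsf1 stays open, untested apart from the group labels.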
